A study of Bos taurus with 18 samples.

How the data were processed

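Total RNA from liver biopsies of 18 Holstein cows, 9 fed rumen-protected niacin and 9 controls, was hybridised to Bovine Gene 1.0 ST arrays (Affymetrix), 1 array per cow. Per the labels' protocols, 22 cows were studied, RNA of 11 cows per group was available, and the 2 samples with the lowest RNA integrity number in each group were left out by the submitters. The integrity number of the 18 samples was 7.2 ± 0.5 (SD), with no value per sample given in the sources used here. Per the submitters' processing notes, the deposited log2 values were made with Affymetrix Expression Console and RMA (background correction, quantile normalization and a summary of each probe set), with versions not given in the sources used here. The log2 scale was taken from the deposited values themselves, which ran from 0.85 to 14.04 with 2 decimals. RMA quantile normalization forces similar distributions on the arrays, so a shift common to most genes would not be visible in these values. Signal intensities and background values per probe were not used here. Samples were assigned to groups by their titles, and cow numbers did not overlap between the groups, so the 18 arrays were treated as 18 independent animals. The labels gave no hybridisation batch, and no parity number or sampling date per cow.

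The table held 24333 probe sets. The platform annotation gave 18457 of them 1 gene symbol, 688 several symbols and 5188 none. By gene ID, 17996 of the single-symbol probe sets matched a RefSeq gene table (assembly ARS-UCD2.0), which changed 0 symbols. Probe sets with several symbols or none were tested but never named by gene. Between arrays, Pearson correlations over all probe sets lay between 0.972 and 0.990 over 153 pairs, and no pair held identical values.

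Analysis was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15. Before the data were examined, the groups, tests, gene lists, rule for named genes and most alternatives were fixed. Probe sets in the lowest share of 0.25 by mean over all 18 arrays were left out (6083, with a mean under 4.35), which left 18250. Each was fitted with lmFit and eBayes, niacin minus control, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05, two-sided. A looser count took probe sets with an unadjusted p under 0.05 and a fold of at least 1.2. The exact permutation p of a gene or list came from all 48620 splits of the 18 arrays into 9 and 9. All fold changes are niacin over control.

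For 21 pathway lists and 11 cell type lists, the score of a cow was the mean log2 value over the measured genes of the list, each gene represented by its brightest probe set with 1 symbol. Scores were compared by the exact two-sided permutation test and adjusted within the pathway lists and within the cell type lists. Their 95% intervals came from the SDs of both groups. Each gene was also adjusted over its list alone. The camera test (estimated correlation, and a preset correlation of 0.01) and the directional fry test were run on the same lists. Some lists share genes: 5 of the 13 measured hepatocyte markers, 1 of 13 macrophage markers (CD14) and 1 of 15 T and NK cell markers (CCL5) also belonged to a pathway list.

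The named genes were the 12 with the smallest unadjusted p and a fold of at least 1.2 in each direction, since 0 genes passed, then in each list the genes past 0.05 over the list alone (at most 4) or otherwise the 2 with the smallest p, and 22 genes of niacin response and liver metabolism fixed by name, of which 20 are reported here.

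The scripts were tested on simulated data with the means and spread of these 18250 probe sets. In the test of genes, errors were drawn independently for each probe set, and 200 probe sets were changed at once. At an adjusted p under 0.05, 6 of 67 probe sets shifted 1.2-fold, 59 of 67 shifted 1.5-fold and 64 of 66 shifted 2-fold were recovered, with 7 calls of unchanged probe sets, and 0 probe sets were called with nothing changed. A list shifted 1.2-fold reached an unadjusted exact p under 0.05 in 80.6% of draws and an unshifted list in 3.44%. Both shares pool all 32 lists. Lists were called by the adjusted p, which is stricter, so 80.6% is an upper bound for calling a list shifted 1.2-fold. The share past the adjusted threshold was not computed.

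Alternatives were other filters on dim probe sets, an intensity trend with robust variances, array weights, a second quantile normalization, centring on the array median, no moderation, a leukocyte marker score as a covariate, other thresholds, other list scores and tests, and leaving out each array in turn. Removing the trend of each array over gene length, and leaving out control 1 and niacin 8 together, were chosen after the data were seen. Gene length was the span of the gene in the RefSeq table, known for 97.5% of the tested probe sets with 1 symbol, and no coordinate was used otherwise.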

Results

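Liver biopsies of 18 multiparous Holstein cows were profiled 1 week after calving on 18 arrays, 1 array per cow. In the niacin group (n = 9) the rations had been supplemented with rumen-protected niacin, a coated form that partly escapes breakdown in the rumen, at 79 mg per kg body weight from 3 weeks before calving. The labels put this at 47 mg per kg at the duodenum and 31 mg per kg absorbable. The control group (n = 9) received the same rations without it. The comparison asks which liver transcripts differ after niacin at this dose. Values are log2 expression per probe set, and array medians lay between 5.57 and 5.72. The number of arrays limits the precision, and the 95% interval of a log2 fold change extended by a median of 0.19 to either side.

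Within the gene lists fixed for liver metabolism, 4 genes differed between niacin-fed and control cows when the adjustment was made over the list alone, and 0 genes did over all genes tested. On leaving out 1 array in turn the 4 became 0 (without control 11, control 36 or niacin 8) to 10 (without niacin 39). SRXN1, which encodes sulfiredoxin, was 1.35-fold higher with niacin (6.54 ± 0.33 against 6.10 ± 0.19, mean ± SD on the log2 scale, n = 9 each). GPX4, a glutathione peroxidase that reduces lipid hydroperoxides, was 1.36-fold higher (9.31 ± 0.29 against 8.86 ± 0.26). APOA5, an apolipoprotein that promotes the clearance of triacylglycerol from plasma, was at 0.715 of the control level (10.58 ± 0.36 against 11.06 ± 0.24). CIDEC, a lipid droplet protein, was at 0.709 of the control level (5.12 ± 0.20 against 5.61 ± 0.39).

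SRXN1 was above the control median in 9 of 9 niacin cows and GPX4 in 8, while CIDEC was below it in 9 and APOA5 in 7. The limma p adjusted over the list alone was 0.0259 for both SRXN1 and GPX4, 0.0345 for APOA5 and 0.0360 for CIDEC. Adjusted over all 18250 probe sets it was 0.453 for each of the 4. With the mean of all leukocyte marker genes as a covariate it was 0.076 for SRXN1, 0.363 for GPX4, 0.437 for APOA5 and 0.498 for CIDEC over the list alone, and 29 of 100 splits of the arrays, the real one included, gave at least 4 such genes. The calls also lay close to the threshold, so that leaving out 1 of several arrays ended them while the log2 fold changes stayed at 0.36 to 0.48 for SRXN1, 0.37 to 0.51 for GPX4, -0.56 to -0.41 for CIDEC and -0.55 to -0.41 for APOA5. SRXN1 lost its call without control 11, 12 or 36 or niacin 8 or 15, and GPX4 without any of these or control 1, with p adjusted over the list alone of 0.0513 to 0.0637. CIDEC lost it without any 1 of 10 arrays (control 1, 11, 23 and 36, niacin 3, 7, 8, 15, 33 and 40; 0.0504 to 0.0917). APOA5 lost it without any 1 of 11 arrays (control 1, 11, 16, 36 and 42, niacin 3, 7, 8, 14, 15 and 19; 0.0574 to 0.0872).

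**Figure D1:**
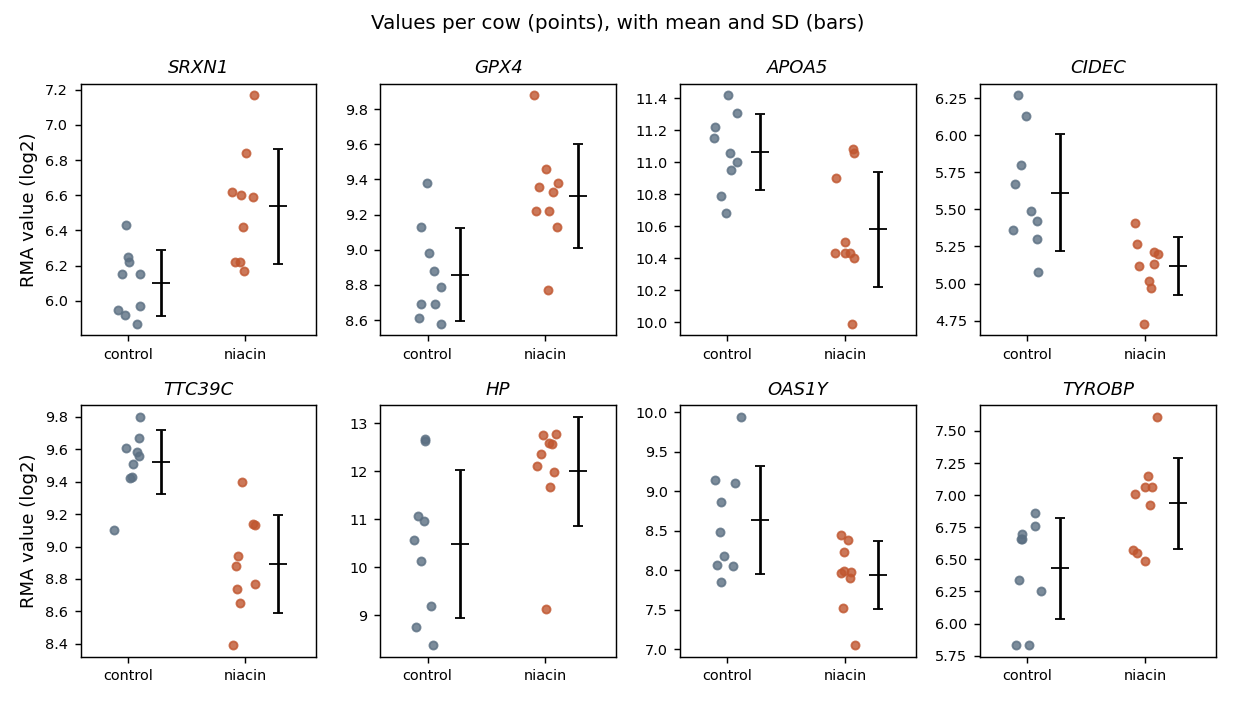
Log2 RMA values of 8 genes in each of the 9 control and 9 niacin cows (points), with the mean and SD of each group (bars); each panel has its own vertical axis, which does not start at 0. SRXN1 and GPX4 were higher and APOA5 and CIDEC lower in the niacin group, with overlap between the groups, and none of the 8 genes passed the test over all probe sets.

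Over all genes, limma found 0 probe sets past an adjusted p of 0.05 among 18250 tested, and the smallest adjusted p was 0.205. At an unadjusted p under 0.05 there were 1413 probe sets (609 higher and 804 lower with niacin), where 912.5 would fall by chance if nothing differed, and 11 of 100 splits of the arrays, the real one included, gave at least as many. The exact permutation test per probe set also gave 0 after adjustment and 1375 at an unadjusted p under 0.05. Of the 609 probe sets with an unadjusted p under 0.05 and a fold of at least 1.2, 192 were higher and 417 lower with niacin (68.5% lower). The lower ones lay mostly in long genes. When probe sets were ranked by the span of their gene and divided into 4 parts of equal size, 133 were lower and 20 higher in the part with the longest genes, against 53 lower and 54 higher in the part with the shortest. In data simulated at this size, with independent errors and 200 probe sets changed at once, 8.96% of probe sets shifted 1.2-fold were recovered. Of those shifted 1.5-fold it was 88.1%, and of those shifted 2-fold 97.0%. Differences near 1.2-fold were thus mostly below what this test could call. With fewer changed probe sets the adjustment is stricter, so these shares may not hold for single genes.

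The genes with the smallest p are given by size and did not pass. TTC39C, a tetratricopeptide repeat protein, came first, at 0.648 of the control level with a log2 fold change of -0.63 ± 0.11 (SE; limma adjusted p = 0.205) and below the control median in 9 of 9 niacin cows. Without niacin 39 it was the single gene to pass, at a log2 fold change of -0.69 and an adjusted p of 0.0353. RBP5, a retinol-binding protein, was the furthest from 1 among these at 0.514 of the control level (-0.96 ± 0.21). PIGA, which acts in the first step of glycosylphosphatidylinositol anchor synthesis, was lower by a log2 fold change of -0.57, the lysosomal enzyme gene GALC by -0.47 and the cytochrome P450 gene CYP2D43 by -0.55. The other genes in this group of 12 were LOC516494 (-0.61), SPTY2D1 (-0.48), TTC36 (-0.48), MON2 (-0.40), THYN1 (-0.40), CBY1 (-0.35) and IMMP2L (-0.32). Their adjusted p lay between 0.205 and 0.383. The 12 genes on the higher side had adjusted p of 0.383 to 0.453. CFAP90 was higher by 0.44, the phospholipase C-like gene PLCL2 by 0.40, the transcription factor gene PAX8 by 0.38, the corepressor gene TLE5 by 0.35 and the 14-3-3 protein gene YWHAH by 0.34. ZFP91 (0.33), MCRIP2 (0.30), the beta-defensin gene EBD (0.28), the ubiquitin ligase gene RNF130 (0.28) and UQCC4 (0.27) followed, beside SRXN1 and GPX4.

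The mean score of each list per cow gave 0 of 32 lists past an adjusted p of 0.05 by the exact two-sided permutation test, and 3 lists had an unadjusted exact p under 0.05. The lipoprotein assembly and secretion score was lower by -0.14 with niacin (exact p = 0.0419, adjusted p = 0.440), and without niacin 8 by -0.11 (exact p = 0.0828). Of its 23 measured genes, 15 were below and 8 above 0, with a median log2 fold change of -0.03, and 6 were lower and 1 higher at an unadjusted p under 0.05, with the largest differences in APOA4 (-0.78) and APOA1 (-0.54), which are named after their values were seen. APOB, the structural protein of very low density lipoproteins, had a log2 fold change of -0.30 ± 0.13 (SE), and MTTP, which loads lipid onto it, -0.27 ± 0.14, or -0.14 without niacin 15. The list of NRF2 targets and antioxidant defence genes was higher by 0.080 (exact p = 0.0276, adjusted p = 0.440), with 3 of 33 genes higher and 2 lower at that threshold, and 20 above and 13 below 0. GPX3, with the largest log2 fold change of the list (1.52 ± 0.72, SE), supplied much of this, and without it the score was higher by 0.035 (exact p = 0.226), a test chosen after the result was seen. Without niacin 39 this list passed, at 0.10 and an adjusted p of 0.0276, and without niacin 8 it was higher by 0.070, with an exact p of 0.0532. The neutrophil marker score was higher by 0.25 (exact p = 0.0358, adjusted p = 0.385), and without niacin 8 by 0.16 (exact p = 0.0727).

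Scores of macrophages and of T and NK cells were on the higher side too, without passing, while that of B and plasma cells hardly differed. The macrophage score was higher by 0.20 (exact p = 0.0802), with 12 of 13 genes above 0, and without niacin 7 by 0.15 (exact p = 0.153). TYROBP, an adaptor of receptors on myeloid cells, was 1.42-fold higher (exact permutation p = 0.0108, higher than the control median in 6 of 9 niacin cows), and C1QB, a subunit of complement C1q, was 1.24-fold higher (exact permutation p = 0.0337). The T and NK cell score was higher by 0.095, with LCK at 0.18 and CCL5 at 0.32 on the log2 scale. The B and plasma cell score differed by 0.0077, or -0.021 without control 1, with BLK at 0.20 and MZB1 at -0.18. In the neutrophil list, S100A12 was 1.92-fold and MMP9 1.16-fold higher, and the log2 fold change of S100A12, 0.94, was 0.61 without niacin 8. Scores of the other cell types differed by -0.038 for hepatocytes, 0.018 for endothelial cells, -0.016 for stellate cells and fibroblasts, -0.033 for bile duct cells, 0.12 for adipocytes and 0.027 for skeletal muscle. The red cell score was higher by 0.26, and by 0.027 without niacin 8. The adjusted p of the cell type scores lay between 0.385 and 0.933. AHSG, a hepatocyte marker that encodes fetuin, had a log2 fold change of -0.27.

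**Figure D2:**
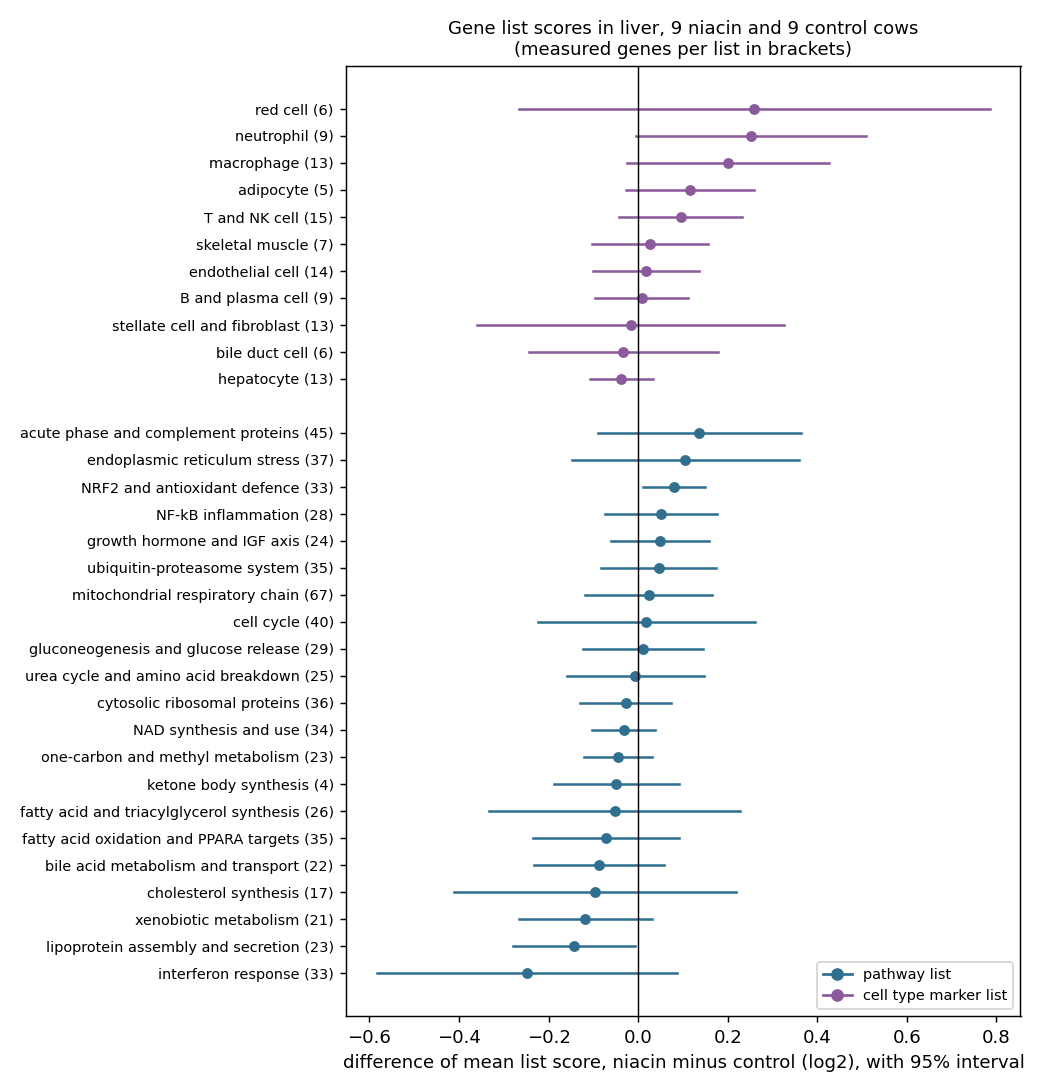
Difference of the mean list score between 9 niacin and 9 control cows on the log2 scale (points) with its 95% interval (lines) for 21 pathway lists and 11 cell type marker lists; the number of measured genes is in brackets. The lipoprotein score lay at -0.14 and the NRF2 and antioxidant score at 0.080, and 0 of 32 lists passed after adjustment.

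The mean interferon response score differed by -0.25 without passing (7.04 ± 0.44 in control against 6.80 ± 0.17 in niacin cows, SD, n = 9 each; exact permutation p = 0.118, adjusted p = 0.620), and the group medians by -0.025. Of 33 genes, 29 had a fold change below 1 and 0 passed over the list alone. OAS1Y, an antiviral oligoadenylate synthetase, had a log2 fold change of -0.69 and RIGI, a sensor of viral RNA, -0.67, and each was below the control median in 9 of 9 niacin cows. Control 1 held the highest interferon score at 8.09, and without it the difference was -0.12 (exact permutation p = 0.236), with 24 of 33 genes below 0, OAS1Y at -0.53 and RIGI at -0.47. The xenobiotic metabolism score was lower by -0.12 (exact p = 0.110), with 6 of 21 genes lower and 0 higher at an unadjusted limma p under 0.05. Among them FMO1, a flavin monooxygenase, was at 0.772 and CYP2C87 at 0.668 of the control level. In the same cows the macrophage score was higher by 0.20 and the neutrophil score by 0.25.

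The list of acute phase and complement genes was higher by 0.14 (exact p = 0.217), and by 0.086 without control 36 (exact p = 0.396), and 0 of its 45 genes passed over the list alone, by limma, where 5 were higher and 1 lower at an unadjusted p under 0.05. HP, haptoglobin, was 2.85-fold higher with niacin (12.00 ± 1.14 against 10.48 ± 1.55, SD, n = 9 each; exact permutation p = 0.0342), and 8 of 9 niacin cows were above the control median, with a limma p adjusted over the list alone of 0.244. C4BPB, a subunit of the complement inhibitor C4b-binding protein, was at 0.675 of the control level, and its limma p adjusted over the list alone was 0.0605. The NF-kB list was higher by 0.051, with TLR2 at 1.19-fold and an adjusted p of 0.0684 over the list alone. The endoplasmic reticulum stress list was higher by 0.11 (exact p = 0.396), and by 0.034 without niacin 14 (exact p = 0.739). Of its 37 genes 30 were above 0, among them the stress transcription factor gene ATF3 (0.39) and CRELD2 (0.33).

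Most of the genes fixed by name for niacin response and liver metabolism had intervals that included 0. HCAR2, the niacin receptor, was at 4.89 ± 0.14 against 4.99 ± 0.15 (SD, n = 9 each), near the level under which probe sets were left out (4.35). NAPRT, the first enzyme of NAD synthesis from niacin, differed by -0.04 with a 95% interval of -0.20 to 0.12. CPT1A, which controls entry of fatty acids into mitochondria, differed by -0.02 (-0.31 to 0.28), FASN, fatty acid synthase, by 0.10 (-0.48 to 0.69) and SCD, a desaturase, by 0.13 (-0.58 to 0.84). FGF21, a hepatokine of negative energy balance, was at 0.546 of the control level, with an interval of -1.81 to 0.07 on the log2 scale. PCK1, which controls gluconeogenesis from oxaloacetate, was lower by a log2 fold change of -0.20 ± 0.09 (SE; exact permutation p = 0.0299, adjusted p = 0.603). PDK4 (-0.34), CYP7A1, the rate-limiting enzyme of bile acid synthesis (-0.46), SIRT1 (-0.17), PPARGC1A (-0.12), IGF1 (-0.08) and ANGPTL4 (-0.02) had intervals that included 0, as had NAMPT (0.12), NNMT (0.16), BHMT (0.13) and PC (0.08). Single cows moved several of these, with NNMT at 0.51 and PDK4 at -0.61 without niacin 15, and CYP7A1 at -0.19 and NNMT at -0.02 without niacin 8. PDK4 was at -0.18 without niacin 14, and NAPRT at -0.08 without control 11 and -0.01 without niacin 15. On leaving out 1 array, FASN reached -0.05, SCD -0.03, PC -0.06, IGF1 0.08, CPT1A 0.04 and ANGPTL4 -0.31 to 0.17, so the sign of these was not settled. PPARGC1A lay between -0.29 and -0.04, while NAMPT reached 0.05 and BHMT 0.06. The sign of PPARGC1A, NAMPT and BHMT held, but with intervals that included 0 it was not settled either.

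Among the pathway lists not described so far, differences with niacin were -0.073 for fatty acid oxidation and PPARA targets, -0.048 for ketone body synthesis, -0.052 for fatty acid and triacylglycerol synthesis, -0.096 for cholesterol synthesis and 0.011 for gluconeogenesis and glucose release. NAD synthesis and use differed by -0.032, one-carbon and methyl metabolism by -0.045, urea cycle and amino acid breakdown by -0.0064, and bile acid metabolism and transport by -0.087. The growth hormone and IGF axis differed by 0.049, the respiratory chain by 0.023, cell cycle genes by 0.018, the ubiquitin-proteasome system by 0.046 and cytosolic ribosomal proteins by -0.027. Without niacin 8 the difference was -0.00040 for fatty acid and triacylglycerol synthesis and -0.0046 for cholesterol synthesis. Over all 32 lists, leaving out 1 array moved the difference by over 1.5 times or to the other sign in 27, and changed the sign in 9. The adjusted p of the 21 pathway lists lay between 0.440 and 0.932. The median fold change of the genes had the other sign than the mean score in 4 lists, namely fatty acid and triacylglycerol synthesis, gluconeogenesis, urea cycle and bile duct cells. Genes with the smallest p in these lists included NMRK1 (-0.25) and NADK (0.31), which act in NAD and NADP synthesis, and GNMT (0.54, or 0.35 without niacin 15) and MAT2A (-0.38), which act in methyl metabolism. The tyrosine breakdown genes HPD (-0.25) and FAH (-0.26), the glucose transporter gene SLC2A2 (-0.33), the bile acid gene CYP8B1 (-0.37, or -0.24 without niacin 8), IGFBP2 (0.34) and the proteasome gene PSMD14 (0.35) belonged here too, and none passed over its list alone.

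Against other genes, camera with a preset correlation called 7 lists. These were interferon response (adjusted p = 2.86e-07), macrophage (6.13e-05), neutrophil (0.00971), lipoprotein (0.0139), xenobiotic metabolism (0.0139), endoplasmic reticulum stress (0.0145) and T and NK cell (0.0340). With an estimated correlation none of the calls held, with an adjusted p of 0.753 for each of the 4 pathway lists, 0.478 for macrophage and neutrophil, and 0.572 for T and NK cell. The directional test of fry gave 0 lists past an adjusted p of 0.05.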

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

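Except for the counts of splits on genes past the threshold over their list alone and on the length of lower genes, the tests used here to weigh explanations were chosen after the results were seen. Single cows stood apart from the rest of their group in 27 of 266 groups of 9 values, that is, in a named gene or a list score the gap to the nearest other cow was more than 0.493 of the range of the group. Chance gives about 1 in 20, or 13.3, if values are normally distributed. The groups of values come from the same 18 cows and from genes that vary together, and some named genes are also part of a list score. The 27 against 13.3 is therefore no test of an excess. Niacin 15 accounted for 9 of the 27, niacin 8 for 7 and control 12 for 5.

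In niacin 15, the ratio of gap to range was 0.592 for MCRIP2 (highest), 0.524 for PEX11A (highest), 0.716 for NADK (highest), 0.671 for RIGI (lowest), 0.610 for NNMT (lowest), 0.515 for PDK4 (highest), 0.667 for MTTP (lowest), 0.554 for PPARGC1A (highest) and 0.647 for the NAD synthesis and use score (lowest). PDK4 was 10.92 in this cow and at most 9.16 in the other niacin cows, and NNMT, which methylates nicotinamide, was 5.62 and at least 8.19. In niacin 8 the ratio was 0.546 for CYP8B1 (lowest), 0.516 for FMO1 (lowest), 0.536 for S100A12 (highest), 0.818 for ALAS2 (highest), 0.645 for CYP7A1 (lowest), 0.622 for the neutrophil score (highest) and 0.866 for the red cell score (highest, 7.23 against at most 5.26). In control 12 it was 0.577 for DECR1 (lowest), 0.524 for PSMD14 (lowest), 0.661 for the xenobiotic metabolism score (lowest), 0.496 for the ubiquitin-proteasome score (lowest) and 0.508 for the stellate cell and fibroblast score (highest). Control 1 was highest for RIGI (0.558) and for the interferon response score (0.613), and control 23 for MON2 (0.614) and for the red cell score (0.567). Control 11 was lowest for NAPRT (0.510), and niacin 39 lowest for HP (0.699), at 9.12 where the other niacin cows had at least 11.68.

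The first pattern is the number of probe sets with small differences and their lean to the lower side. Chance cannot be excluded for the count, since 9 of 100 splits of the 18 arrays, the real one counted here and below, gave at least 609 probe sets (highest other 1468), nor for the share one way, since 5 of 100 reached 68.5% (highest other 77.1%), while for the 0 genes past an adjusted p of 0.05 the splits decide nothing, since each of the 100 gives at least 0 (highest other 7). Removing a trend over gene length from each array left 66.9% lower. This decides little, since the trend was small, with a median log2 fold change of 0.032 for the shortest genes and -0.022 for the longest. Array scaling stays open too, since the array medians differed by 0.0044 between the groups and centring on them, which left 72.0% lower, could move little. The gap between the longest and shortest genes in the share lower, 37.4 percentage points, was matched in either direction by 26 of 100 splits (highest other 73.7), so such gaps arise between groups of these cows drawn at random, and differences in RNA integrity between samples may contribute, which could not be tested without a value per sample. An effect of niacin remains open, as for the 4 genes past the threshold over their list alone, a number that 29 of 100 splits reached (highest other 34).

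The second pattern is the higher macrophage, neutrophil and T and NK cell scores in niacin-fed cows, which did not pass after adjustment. More blood in the biopsies could not be settled as a cause. The red cell score as a covariate removed -0.0033 (95% interval -0.065 to 0.058) of the macrophage difference of 0.20. For the neutrophil markers it removed 0.10 (0.059 to 0.14) of 0.25, and the mean of the haemoglobin genes HBA and HBB removed 0.086 (0.047 to 0.12). These values rest on niacin 8, which held most of the red cell difference. Without niacin 8 the red cell score removed -0.015 (-0.031 to 0.0023) of 0.19 for macrophages and 0.0078 (-0.0051 to 0.021) of 0.16 for neutrophils. There it differed by 0.027 between the groups, so it could remove little whatever the cause, and blood and diet cannot be told apart. A lower share of hepatocytes would raise markers of the other cell types alike, and the macrophage score minus the mean of the endothelial, stellate and bile duct scores was higher by 0.21 in niacin cows, but with an exact permutation p of 0.0902 this too cannot be told apart at 9 cows per group. An effect of niacin on these cells stays open, as untested.

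The third pattern is the lower mean interferon score, which did not pass. The difference of the group means was -0.25, and -0.12 without control 1 (exact permutation p = 0.236), while that of the group medians, which 1 cow hardly moves and which was chosen as a further test later, was -0.025. This goes with control 1 as a main source of the difference in the score. Without that cow 24 of 33 genes of the list were still below 0, OAS1Y at -0.53 and RIGI at -0.47. The genes of this list vary together (estimated correlation 0.58), and OAS1Y and RIGI had the smallest p in it. The count and these 2 genes are therefore no separate evidence of a lower list score beyond control 1. For OAS1Y and RIGI themselves that cow was the smaller part, since they were at -0.69 and -0.67 with it. As they were picked by their p, this is no test of a difference. A smaller effect of niacin stays open, as untested.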

How the results depend on the processing

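Removing the gene length trend and leaving out control 1 and niacin 8 together were tests chosen after the results were seen. The count of genes past an adjusted p of 0.05 by limma was 0 under each alternative other than leaving out 1 array, and the looser count at an unadjusted p under 0.05 and a fold of at least 1.2 was 609. Leaving out 1 array in turn gave 0 to 1 genes (1, TTC39C, without niacin 39), 0 to 1 lists (1, the NRF2 and antioxidant list, without niacin 39) and 483 (without control 23) to 811 (without niacin 39) probe sets in the looser count. That count was 377 with the leukocyte marker score as a covariate, 229 at a fold of at least 1.3 and 54 at a fold of at least 1.5. The last pair are smaller by construction, and the cause of the first was not tested. Other alternatives gave 441 (gene length trend removed) to 765 (no filter), with 59.8% (array weights) to 72.0% (arrays centred on their median) lower. These ends tested 14430 and 24333 probe sets, so their counts cannot be set directly against 609 of 18250. Those with all 18250 tested gave 452 (control 1 and niacin 8 left out) to 599 (arrays centred on their median). With the leukocyte marker score as a covariate the smallest adjusted p was 0.999, and p adjusted over the list alone was 0.076 for SRXN1, 0.363 for GPX4, 0.437 for APOA5 and 0.498 for CIDEC. Without moderation it was 0.0629, 0.0629, 0.0914 and 0.0978, and without control 1 and niacin 8 it was 0.106 to 0.135, so none of the 4 calls held there. Lists past the threshold numbered 0 in all settings except 7 by camera with a preset correlation and the 1 without niacin 39. As 0 genes over all probe sets and 0 lists passed in the main analysis, no direction called there could reverse. Of 101 named genes, the sign differed in 6 with the leukocyte marker score as a covariate and in 4 without control 1 and niacin 8. Without these 2 cows it also differed in 6 of 32 lists. No paired or blocked analysis was possible because the labels give no pairing or block of cows.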

Other observations

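The genes and tests below were chosen after the results were seen, except that the count of splits for the cytochrome P450 genes was set before its value was known. Of the 18250 probe sets, 10 differed by a fold of at least 2, and none passed after adjustment. Besides HP, the named ones on the higher side were the extracellular glutathione peroxidase gene GPX3 (2.87-fold, 8 of 9 niacin cows above the control median), the endopeptidase gene ECEL1 (2.67-fold, 9 of 9), the acute phase gene SAA3 (2.47-fold, 8 of 9), the imprinted gene NNAT (2.40-fold, 8 of 9) and the acute phase inhibitor gene SERPINA3-7 (2.31-fold, 7 of 9). On the lower side were CYP2C85 (0.486 of the control level) and CABYR (0.492), each below the control median in 8 of 9. The spread between cows was wide for these genes, with an SD of 1.98 in control and 1.52 in niacin cows for GPX3 on the log2 scale, and exact permutation p of 0.0869 for GPX3, 0.0353 for ECEL1, 0.0581 for SAA3, 0.0120 for NNAT, 0.178 for SERPINA3-7, 0.0153 for CYP2C85 and 0.00889 for CABYR.

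Genes were grouped by the letters that open their symbols into 156 families of at least 10 tested genes. Of 36 cytochrome P450 genes, 7 were lower with niacin at an unadjusted p under 0.05 and a fold of at least 1.2 (CYP2D43, CYP2C85, CYP3A76, CYP39A1, CYP2C87, CYP8B1 and CYP2D14) and 1 was higher, against 339 lower among 14487 genes (one-sided Fisher's exact test, adjusted p = 0.00262). No other family passed. That test takes genes as independent, which members of one family are not. Chance cannot be excluded, since 7 of 100 splits of the arrays, the real one included, gave at least 7 cytochrome P450 probe sets in 1 direction (highest other 8).

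A principal component analysis of the tested probe sets placed the groups apart on component 2, which held 12.1% of the variance (7.11 ± 9.61 in control and -7.11 ± 10.0 in niacin cows, SD, n = 9 each; exact permutation p = 0.00267, adjusted p = 0.0160 over 6 components). On leaving out 1 array in turn the exact p lay between 0.000123 and 0.0142, except without control 1, where it was 0.140. Of 5 relations between scores computed across the 18 cows, component 2 followed the slope of the values of each array over gene length (r = 0.735, permutation p = 0.00035, adjusted p = 0.00175; rho = 0.628, permutation p = 0.00644, adjusted p = 0.0322). Without the 2 cows with the most extreme slope r was 0.69, and within groups it was 0.836 in control and 0.555 in niacin cows. Both values come from the same arrays and are not independent measures. The slope itself was 0.015 ± 0.036 in control and -0.015 ± 0.040 in niacin cows (SD, n = 9 each; exact permutation p = 0.119).

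The neutrophil and red cell scores had r = 0.801 (permutation p = 0.00523, adjusted p = 0.0131) and rho = 0.395 (permutation p = 0.105, adjusted p = 0.175), and r was 0.466 without the 2 cows with the most extreme neutrophil score, so the relation rested on them. The acute phase and xenobiotic metabolism scores had r = -0.526 (permutation p = 0.0247, adjusted p = 0.0412; -0.528 without the 2 cows with the most extreme acute phase score) and rho = -0.453 (permutation p = 0.0609, adjusted p = 0.152), with r of -0.489 within control and -0.428 within niacin cows. Control 12, flagged above for its low xenobiotic score (9.07) and with an acute phase score of 11.39, was kept in these values except the niacin one. The r within control leaned on this cow. Control 23 also had an acute phase score of 11.39, with a xenobiotic score of 9.48. Control 36, with the lowest acute phase score (10.63), had 9.46. The relation without control 12 was not tested, so the r within control is no separate support for it. The lipoprotein score showed no relation past the threshold with the acute phase score (r = 0.035, permutation p = 0.892, adjusted p = 0.892; rho = 0.061, permutation p = 0.812) or the macrophage score (r = -0.227, permutation p = 0.363, adjusted p = 0.454; rho = -0.262, permutation p = 0.290). Values varied more between niacin cows than between control cows in 59.1% of probe sets, which was not tested.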
